A study of Mus musculus with 9 samples.

How the data were processed

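RNA of the left liver lobe of 9 male mice was sequenced with the QuantSeq 3' kit, 3 mice in each of 3 groups. Groups were taken from the sample titles and the study's description. The treatment label of the chow and STAM samples contradicts both and was not used. Per the labels, the authors aligned reads with STAR to the mouse genome GRCm38. The version of STAR, the counting tool, the annotation release and the handling of strand and of reads that map to several places are not given in the sources used here. The deposited table holds raw read counts per gene from the authors for each of the 9 libraries, and their sums per group, which equalled the sums of the 3 libraries for every gene. It also holds the authors' own log2 fold changes with standard errors, and the authors' unadjusted and adjusted p-values, deposited under column names that DESeq2 writes, though no tool is named. Their column of mean scaled counts was not used.

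The table has 55401 genes, of which 20630 had at least 1 count, and 7 entries for ribosomal RNA, which were left out of the tests and held 0.260 to 0.529% of counts. In units of 1e6 counts, totals were 7.41 to 9.91 per library (mean 8.85 ± 0.755 SD), and the 10 most abundant genes took 19.3 to 21.4%. Of the gene identifiers, 55141 were found in the GENCODE M21 annotation of GRCm38 from which positions and overlaps were taken, and 4 tested genes were not in it. Intervals and floors cover counting error only, and a floor is 3 counts over a group.

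Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr on the groups (12660 genes kept), 1 fit to all 9 samples with group means, and quasi-likelihood tests of 3 comparisons with Benjamini-Hochberg adjustment over all tested genes. A gene passed at an adjusted p under 0.05. CPM values use TMM-scaled library sizes. The common biological coefficient of variation was 0.236. A set of 41 gene lists of pathways, cell types and sample quality was fixed before the data were examined, as were the tests, the comparisons and the rule for named genes. The 37 lists with at least 5 tested genes were compared with all other genes by limma 3.58.1 camera, with a preset correlation of 0.01 between genes, two-sided, and adjusted over lists. An estimated correlation and fry, which asks whether the genes of a list move one way, were run beside it. List scores are mean log2 CPM of the tested members relative to the chow mean. Genes changed back were those past the threshold in STAM against chow and, in the opposite direction, in STAM + Atglistatin against STAM.

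Named genes in each of the first 2 comparisons were the 6 higher and 6 lower with the largest fold changes among genes that passed, had a mean log2 CPM of at least 3 and had values that did not overlap between the 2 groups. To these were added, from the lists with at least 3 members passing one way, the 3 members with the smallest p in that direction of each of the 8 with the largest share, up to 2 members of other lists, and 17 genes fixed in advance for their part in lipolysis, PPARa signalling, bile acids, fibrosis and inflammation. For STAM + Atglistatin against chow only those 17 were named, apart from genes already named, and for genes changed back the 5 in each direction with the smallest larger p. Some genes that this rule selects are not used here.

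The alternatives were DESeq2 size factors, no low-count filter, DESeq2 1.42.0, limma-voom with sample weights, a fit to the 2 groups compared, an absolute log2 fold change of at least 1, and leaving out each library in turn. Library totals without TMM were added after the data were seen. On simulated data with the spread of these libraries, the test recovered 51.6 to 53.6% of genes changed by a log2 fold change of 1 and 77.6 to 82.1% of those changed by 2, and 5.67 to 7.41% of calls were of unchanged genes. With no effect simulated it called a mean of 0.3 to 0.5 genes over 20 runs.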

Results

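Liver RNA from the left lobe of 9 male mice was measured by QuantSeq 3' mRNA sequencing, a method that reads the 3' ends of transcripts, in 3 groups of 3 mice. Chow mice were healthy controls. STAM mice, a model of diabetes with fatty liver disease, received 200 µg of streptozotocin at 2 days of age and ate a high-fat diet for 4 weeks from 4 weeks of age. STAM + Atglistatin mice were treated alike, with Atglistatin, an inhibitor of adipose triglyceride lipase (the product of Pnpla2), mixed into the high-fat diet. In units of 1e6 counts, the library totals were 7.41 to 9.91, with a mean of 8.85, and 12660 genes had enough counts to be tested. Values are counts scaled to 1e6 per library (CPM) as mean ± SD of n = 3 mice, or log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p. Each gene named as having risen or fallen lay, in all 3 libraries of the first group, beyond all 3 of the second, which chance gives for 10% of genes in a design of 3 against 3. For the genes with the largest changes this was a condition of being named, and list members were chosen by smallest p. The separation is therefore no further support for these genes. The share of counts from mitochondrially encoded transcripts was 7.98 ± 0.738% in chow, 11.2 ± 0.303% in STAM and 9.04 ± 0.600% in STAM + Atglistatin. Some of these transcripts had 0 counts in every library, so the share covers only part of them. Chow replicate 7 stood apart from the other chow libraries, with a proliferation list score of 1.33 against -0.70 and -0.63, and a score for recruited macrophages of 1.12 against -0.74 and -0.38.

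STAM against chow asked how the diabetic, high-fat-fed liver differed from the healthy one. Genes of cholesterol synthesis were far lower in STAM. Cyp51, the lanosterol demethylase of the pathway, stood at 221 ± 17.5 CPM in chow and 27.2 ± 4.87 in STAM (n = 3 each), an 8.11-fold drop. Sqle, squalene epoxidase, fell 17.7-fold from 74.9 ± 10.7 to 4.22 ± 2.19 CPM. In the other direction, Cfd, the complement factor adipsin, rose 33.1-fold from 4.51 ± 1.74 to 149 ± 37.2 CPM, and Cyp4a14, a fatty acid hydroxylase induced through the fatty acid sensor PPARa, rose 8.18-fold from 120 ± 69.0 to 988 ± 279 CPM.

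Of the 25 cholesterol synthesis genes tested, 23 fell and none rose, and 25 fell when adjusted over the list alone. The list's median log2 fold change was -1.90 (limma camera adjusted p = 5.93e-62, and adjusted p = 0.00166 with an estimated correlation). Log2 fold changes were -4.15 ± 0.31 for Sqle, -3.26 ± 0.23 for the farnesyl diphosphate synthase gene Fdps, and -3.02 ± 0.16 for Cyp51 (edgeR adjusted p = 5.00e-09). Nsdhl and Msmo1, which act on sterols after lanosterol, fell by 2.74 ± 0.18 and 2.24 ± 0.15. Sqle lies on chromosome 15 (59315077 to 59331192, plus strand) and Cyp51 on chromosome 5 (4081145 to 4104746, minus strand) of GRCm38. Cyp51 overlaps Akap9 on the other strand, and the strand use of the counting is not stated. Among 23 fatty acid and triglyceride synthesis genes, 13 fell and 0 rose (15 fell adjusted over the list alone), with a median of -0.82 (limma camera adjusted p = 9.70e-21, but adjusted p = 0.0642 with an estimated correlation). Scd1, stearoyl-CoA desaturase (chromosome 19, 44394455 to 44407879, minus strand), went from 6198 ± 1469 to 652 ± 159 CPM, and Acss2, which overlaps Gss on the other strand, fell by 2.39 ± 0.18 and Acacb by 2.10 ± 0.20.

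Of 25 PPARa targets, 14 rose and 0 fell (17 rose and 1 fell adjusted over the list alone), with a median of 0.56 (limma camera adjusted p = 6.67e-24, and adjusted p = 0.0136 with an estimated correlation). Vnn1, a pantetheinase, rose by 1.73 ± 0.14, Aldh3a2, a fatty aldehyde dehydrogenase, by 1.49 ± 0.13, Cyp4a10 by 2.20 ± 0.22 and Cyp4a14 by 3.03 ± 0.35. Cyp4a10 has close relatives in its family, and how reads shared between copies were counted is not stated. Of 23 mitochondrial fatty acid oxidation genes, 8 rose and 0 fell (15 rose adjusted over the list alone; 4 rose without STAM replicate 1, and 13 with library totals in place of TMM). Their median was 0.38 (limma camera adjusted p = 1.88e-13, but adjusted p = 0.0744 with an estimated correlation), and the named members were Cpt1a (0.82 ± 0.12), Hadh (0.71 ± 0.12) and Decr1 (0.66 ± 0.12). Among 12 genes of PPARg and lipid uptake, 5 rose and 0 fell (8 rose adjusted over the list alone, and 8 without chow replicate 7), with a median of 0.97 (limma camera adjusted p = 2.85e-11, and adjusted p = 0.0336 with an estimated correlation). The fatty acid transporter Cd36 (chromosome 5, 17781690 to 17888801, minus strand) went from 19.6 ± 6.23 to 94.3 ± 7.97 CPM, and Fabp2 rose by 0.89 ± 0.11. Cidea, a lipid droplet protein, had 1 count over the chow libraries, in replicate 7, and 238 over the STAM libraries, a ratio of 228 (95% exact interval 40.6 to 9055, counting error only). Of 20 lipolysis and lipid droplet genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone; 2 rose without chow replicate 8 or 9 or STAM replicate 1 or 3), with a median of 0.29 (limma camera adjusted p = 0.00365, but adjusted p = 0.265 with an estimated correlation). Pnpla2, the target of Atglistatin, had a log2 fold change of 0.43 ± 0.18 (edgeR adjusted p = 0.265) and Ppara one of 0.33 ± 0.17 (edgeR adjusted p = 0.397). Neither passed.

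Bile acid genes went both ways. Of 16 bile acid synthesis genes, 0 rose and 3 fell (2 and 3 adjusted over the list alone), with a median of -0.19 (limma camera adjusted p = 0.0384, but adjusted p = 0.538 with an estimated correlation). Cyp2c70, which makes muricholic acids in mice (chromosome 19, 40153353 to 40187333, minus strand), went from 556 ± 98.8 to 149 ± 26.7 CPM, a log2 fold change of -1.90 ± 0.17 (edgeR adjusted p = 1.25e-06). Cyp27a1, which starts the acidic route, fell by 0.65 ± 0.13, and Cyp39a1 by 1.48 ± 0.35. Cyp7a1, the rate-limiting enzyme, had a fold change of -0.09 ± 0.29, Cyp7b1 one of -0.22 ± 0.17, and Cyp8b1, the sterol 12-hydroxylase, one of 0.62 ± 0.18 (edgeR adjusted p = 0.0624), and none of these passed. Cyp8b1 passed with DESeq2 (adjusted p = 0.0156), limma-voom (0.0276), library totals (0.0196), no low-count filter (0.000226) and without chow replicate 9 (0.0215), and its adjusted p ranged up to 0.282 over 12 alternatives. Of 16 bile acid and sterol transporters, 5 rose and 3 fell (5 and 4 adjusted over the list alone; limma camera adjusted p = 0.746). Without chow replicate 7, 3 rose and 6 fell, and 3 rose without chow replicate 8 or 9 or STAM replicate 1 or 2. Abcb4, the phospholipid exporter into bile, rose by 0.70 ± 0.12, and Abcg5, a sterol exporter that overlaps Abcg8, by 0.83 ± 0.15. Abcg2 rose by 0.59 ± 0.14 (edgeR adjusted p = 0.0209), a call lost without chow replicate 7 or any STAM replicate (adjusted p = 0.0511 to 0.0886; range over 12 alternatives 0.00218 to 0.0886). The bile salt export pump Abcb11 fell by 1.03 ± 0.13. The uptake carrier Slc10a1 (-0.42 ± 0.19) and the FXR target Nr0b2 (-0.20 ± 0.25) did not pass, though Slc10a1 passed without chow replicate 7 (-0.68, edgeR adjusted p = 0.00157, in a range up to 0.737 over 12 alternatives). Of 11 FXR and bile acid regulators, 1 rose and 1 fell (2 and 1 adjusted over the list alone; limma camera adjusted p = 0.915). These were Nr1i3 (0.89 ± 0.21), a call lost without chow replicate 9 or STAM replicate 3 (edgeR adjusted p = 0.0622 and 0.155) or with only the 2 groups fitted (0.0502; lowest of 12 alternatives 1.75e-07), and Fgfr4 (-1.04 ± 0.21), lost without chow replicate 8 (edgeR adjusted p = 0.0515, in a range from 0.00173 over 12 alternatives). Nr1i3 overlaps Tomm40l on the other strand.

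The other genes with the largest changes were Cyp2b9 (0.666 ± 0.578 to 24.6 ± 10.5 CPM), the sulfotransferase gene Sult2a7 (4.65 ± 0.37), the imprinted long noncoding RNAs H19 (4.32 ± 0.63) and Meg3 (4.05 ± 0.53), and the oxysterol-binding protein gene Osbpl3 (3.26 ± 0.37), all higher in STAM. All 13 chow counts of H19 lay in chow replicate 7, so that without it the fitted value (9.51) is no bound. Fabp5 fell by 3.46 ± 0.44 and Cyp2b10 by 3.38 ± 0.38. Without chow replicate 7 the fold change was 5.04 for Meg3 and 4.61 for Cyp2b9 (5.29 with all libraries), without chow replicate 8 it was 5.41 for Sult2a7, without chow replicate 9 it was -2.84 for Fabp5, and without STAM replicate 3 it was -4.19 for Cyp2b10. Of 16 general hepatocyte genes, 0 rose and 7 fell (11 fell adjusted over the list alone, and 11 with limma-voom or no low-count filter), with a median of -0.49 (limma camera adjusted p = 2.17e-13, but adjusted p = 0.1 with an estimated correlation). Alb went from 60367 ± 3647 to 29475 ± 2539 CPM, Apoa1 fell by 0.80 ± 0.11 and Ttr by 0.72 ± 0.11. The mitochondrial share of counts was higher in STAM by the values given above, and of 8 mitochondrially encoded transcripts 2 rose and 0 fell (5 rose adjusted over the list alone), with a median of 0.32 (limma camera adjusted p = 0.000240, but adjusted p = 0.251 with an estimated correlation). Of 18 liver genes known to be higher in males, 0 rose and 7 fell (2 and 9 adjusted over the list alone), with a median of -0.52 (limma camera adjusted p = 4.09e-07, but adjusted p = 0.251 with an estimated correlation), among them Serpina1e (-2.19 ± 0.28), Hsd3b5 (-2.63 ± 0.40) and Elovl3 (-1.59 ± 0.25). Of 10 female-biased genes, 3 rose and 0 fell (4 rose adjusted over the list alone), with a median of 1.04 (limma camera adjusted p = 0.00539, but adjusted p = 0.1 with an estimated correlation). Cyp2b9, Cyp2b10, Sult2a7 and Serpina1e belong to families of similar genes.

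Genes of fibrosis and matrix (25 tested), proliferation (23) and antigen presentation by MHC class II (8) had 0 calls by edgeR, by DESeq2, by limma-voom and at an unadjusted p under 0.05. Of 18 inflammatory cytokine and chemokine genes, 0 passed in edgeR, 1 fell at an unadjusted p under 0.05, 1 fell in DESeq2 and 0 passed in limma-voom. Camera's adjusted p was 0.863 for fibrosis, 0.721 for proliferation, 0.721 for MHC class II and 0.560 for the inflammatory list. Col1a1, the main collagen gene, was at 35.9 ± 30.4 CPM in chow and 34.0 ± 14.6 in STAM, and its small difference changed sign with limma-voom (0.42). The fibrosis score of chow replicate 7 was 0.74, against -0.46 and -0.28 in the other chow libraries. The STAM libraries lay between these, at -0.16 to 0.20. Summed CPM of proliferation genes was likewise 116 to 139 in STAM, against 244 in chow replicate 7 and 85.0 and 94.1 in the other chow libraries. No calls for these lists are given without chow replicate 7, so their absence does not exclude a rise hidden by that library. The chemokine Ccl2 (-1.48 ± 0.84) and the hormone Fgf21 (-2.14 ± 1.13) did not pass. Fgf21 passed with no low-count filter (edgeR adjusted p = 0.0135, in a range up to 0.673 over 10 alternatives), and with limma-voom its sign turned (1.66). Its chow signal lay almost all in replicate 7 (13.8 CPM, against 0 and 0.148 in the others). Tnf had 1 count in all chow libraries together and 1 in all STAM libraries, too few to compare at this depth. Of 24 interferon response genes, 5 rose and 0 fell (7 rose adjusted over the list alone), with a median of 0.34 (limma camera adjusted p = 0.000463, but adjusted p = 0.127 with an estimated correlation). The interferon count was 0 without chow replicate 8 or 9 or STAM replicate 3, and 1 without STAM replicate 1 or 2. Of 19 ER stress genes, 0 passed in edgeR (1 up and 7 down at an unadjusted p under 0.05, 1 up in DESeq2, 1 down in limma-voom), with a median of -0.30 (limma camera adjusted p = 0.0151, but adjusted p = 0.383 with an estimated correlation). The ER stress list score in STAM was 0.011 ± 0.153, of the other sign than this median.

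In all, 499 genes passed in STAM against chow, 247 higher and 252 lower, and 1841 had an unadjusted p under 0.05. With library totals in place of TMM, 347 were higher and 205 lower, with limma-voom 405 were lower, and with no low-count filter 373 were higher. The count was 291 without STAM replicate 1 and 312 without STAM replicate 2, with 140 and 147 higher and 151 and 165 lower, and 147 were higher without STAM replicate 3. Without chow replicate 7 it was 724. The deposited table of the authors held 627 genes under an adjusted p of 0.05, of which 485 were among the 499, all in the same direction. Of 37 lists tested, 14 passed limma camera, 8 higher and 6 lower, and 3 passed with an estimated correlation: cholesterol synthesis, PPARa targets, and PPARg and lipid uptake. Of the lists that passed camera, the list score of all 3 STAM libraries lay beyond every chow library, except for bile acid synthesis, interferon response and mitochondrially encoded transcripts (2 of 3) and ER stress (0 of 3).

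**Figure D1:**
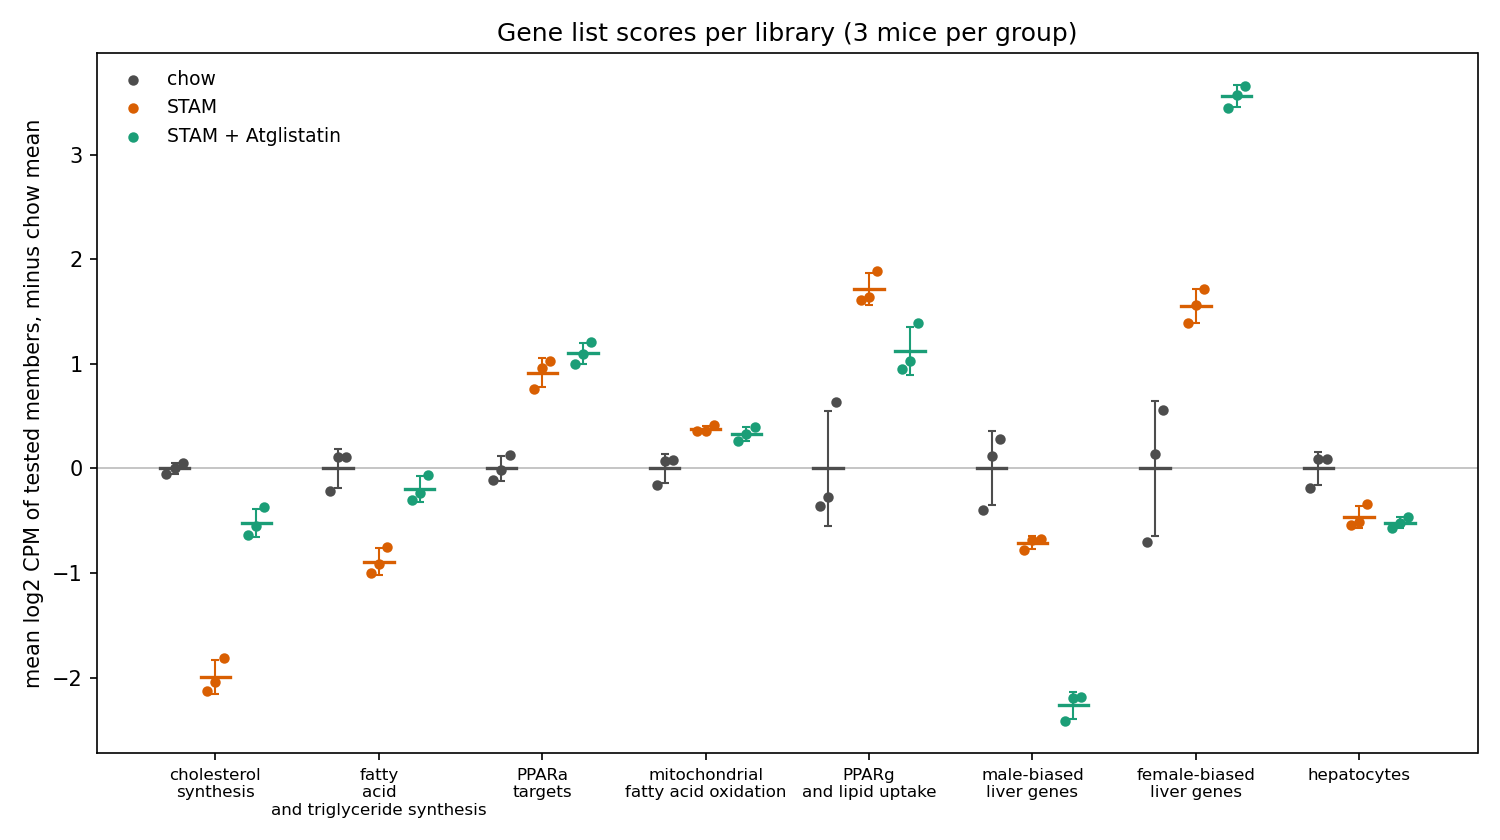
Mean log2 CPM of the tested members of 8 gene lists in each library, relative to the chow mean, with points for the 9 mice, bars for group means and error bars for SD (n = 3). The cholesterol synthesis score was -1.99 ± 0.16 in STAM and -0.52 ± 0.14 in STAM + Atglistatin, while the PPARa target score was 0.91 ± 0.14 and 1.10 ± 0.10.

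STAM + Atglistatin against STAM asked what the lipase inhibitor changed in the liver of the model, including PPARa signalling and bile acid genes. Cholesterol synthesis genes were higher with the inhibitor: Cyp51 rose 4.73-fold, from 27.2 ± 4.87 to 129 ± 17.8 CPM, and Sqle 7.45-fold, from 4.22 ± 2.19 to 31.5 ± 9.20 CPM (n = 3 each). Genes known to be higher in male liver were lower: Hsd3b5, a steroid-metabolising enzyme (chromosome 3, 98618634 to 98630252, minus strand, overlapping Zfp697 on the other strand), went from 36.9 ± 9.01 to 4.80 ± 4.92 CPM (-2.93, and -4.19 without STAM + Atglistatin replicate 4). Cfd (chromosome 10, 79890853 to 79892655, plus strand) dropped 27.4-fold, from 149 ± 37.2 to 5.44 ± 1.77 CPM. PPARa targets as a list did not pass, and Pnpla2, the gene of the inhibited enzyme, was at 69.9 ± 8.15 CPM in STAM and 69.7 ± 19.7 with Atglistatin.

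Of 25 cholesterol synthesis genes, 21 rose and 0 fell (24 rose adjusted over the list alone), with a median of 1.46 (limma camera adjusted p = 2.21e-53, and adjusted p = 0.00444 with an estimated correlation). Log2 fold changes were 2.90 ± 0.30 for Sqle, 2.24 ± 0.15 for Cyp51 (edgeR adjusted p = 1.16e-07), 2.45 ± 0.22 for Fdps and 1.61 ± 0.15 for Msmo1. Of 23 fatty acid and triglyceride synthesis genes, 13 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.76 (limma camera adjusted p = 1.01e-20, and adjusted p = 0.0487 with an estimated correlation). Fasn, the fatty acid synthase, went from 214 ± 56.2 to 979 ± 197 CPM, Scd1 from 652 ± 159 to 2241 ± 538 CPM, and Acly rose by 1.21 ± 0.16.

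Of 18 male-biased liver genes, 0 rose and 15 fell (16 fell adjusted over the list alone), with a median of -1.61 (limma camera adjusted p = 1.80e-37, and adjusted p = 0.0200 with an estimated correlation). Selenbp2 went from 320 ± 68.5 to 51.5 ± 7.26 CPM, Cyp4a12a fell by 2.03 ± 0.17 and Cyp4a12b by 2.79 ± 0.18. The major urinary protein genes named among the largest drops lie outside this list: Mup9 (-3.73 ± 0.31), Mup12 (-3.19 ± 0.39) and Mup11 (-3.12 ± 0.23), of which Mup12 did not pass in limma-voom (adjusted p = 0.0650, the highest of its 12 alternatives, against a lowest of 1.17e-14). Of 10 female-biased genes, 5 rose and 0 fell (7 rose adjusted over the list alone), with a median of 1.71 (limma camera adjusted p = 2.60e-13, and adjusted p = 0.00444 with an estimated correlation). Acot3 went from 25.8 ± 13.7 to 83.0 ± 10.2 CPM. Cyp2b9 (1.44 ± 0.30, edgeR adjusted p = 0.0149) and Cyp2a4 (2.97 ± 0.68, edgeR adjusted p = 0.0299) did not pass with DESeq2 (adjusted p = 0.296 and 0.661, each the highest of 12 alternatives), where 3 members of the list rose. The lowest adjusted p over those alternatives was 4.32e-11 for Cyp2b9 and 2.19e-81 for Cyp2a4. Values so far below those of the main fit, from 3 mice per group, are no measure of the strength of these calls. Treated libraries were at 332 to 550 CPM for Cyp2a4 and STAM libraries at 51.8 to 62.2. In chow, part of the same fit, Cyp2a4 was at 31.1 CPM in replicate 7 and 0 to 0.296 in the others. With only the 2 groups compared fitted, which leaves chow out, the edgeR calls of Cyp2a4 and Cyp2b9 both held. The calls of Cyp2b9 and Cyp2a4 were lost without STAM + Atglistatin replicate 4 or 5 or STAM replicate 1 or 2, and that of Cyp2a4 also without STAM replicate 3 (edgeR adjusted p = 0.0716 to 0.0941 for Cyp2b9 and 0.117 to 0.203 for Cyp2a4). The female-biased count was 2 without STAM + Atglistatin replicate 5 or STAM replicate 1, and 3 without STAM + Atglistatin replicate 4 or STAM replicate 2 or 3. The Mup, Cyp2a, Cyp2b and Cyp4a families hold closely similar genes, so values of single members are uncertain.

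Of 18 xenobiotic genes under the receptors CAR and PXR, 6 rose and 0 fell (7 rose adjusted over the list alone), with a median of 0.45 (limma camera adjusted p = 5.75e-15, and adjusted p = 0.0265 with an estimated correlation). Cyp1a2 went from 651 ± 13.2 to 2145 ± 328 CPM, Cyp2a5 rose by 1.22 ± 0.13 and Gstm2 by 1.17 ± 0.16. Of 18 NRF2 and antioxidant genes, 5 rose and 0 fell (6 rose adjusted over the list alone), with a median of 0.36 (limma camera adjusted p = 1.38e-05, but adjusted p = 0.142 with an estimated correlation). Gstm1 rose by 1.46 ± 0.16, Gsta4 by 1.04 ± 0.17 and Gstm3 by 2.01 ± 0.45 (edgeR adjusted p = 0.0256). The NRF2 count was 2 without STAM + Atglistatin replicate 4 or 5 or STAM replicate 1 or 2, and 3 without STAM + Atglistatin replicate 6 or STAM replicate 3. Gstm3 and Cdkn1a, the gene of the cell-cycle inhibitor p21 (24.2 ± 5.13 to 154 ± 14.7 CPM, edgeR adjusted p = 0.0150), did not pass with DESeq2 (adjusted p = 0.126 and 0.123). Both were also lost without STAM + Atglistatin replicate 4 or 5 or any STAM replicate (edgeR adjusted p = 0.0683 to 0.156 for Gstm3 and 0.0508 to 0.121 for Cdkn1a), and the lowest adjusted p over 12 alternatives was 1.57e-40 for Gstm3 and 3.06e-52 for Cdkn1a. Both calls held with only the 2 groups compared fitted, which leaves chow out. Chow replicate 7 was at 435 CPM for Gstm3, above the treated libraries (260 to 379), and the other chow libraries were at 77.6 and 85.3. For Cdkn1a, chow replicate 7 was at 50.4 CPM and the others at 2.89 and 6.35.

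Of 25 PPARa targets, 1 rose (Acot3, 1.69 ± 0.28) and 0 fell (2 rose and 1 fell adjusted over the list alone), with a median of 0.02 (limma camera adjusted p = 0.313, and adjusted p = 0.737 with an estimated correlation). Cyp4a14 was at 988 ± 279 CPM in STAM and 1452 ± 123 with Atglistatin (0.56 ± 0.32, edgeR adjusted p = 0.614), and passed with no low-count filter (adjusted p = 0.00155, in a range up to 0.911). Cyp4a10 (-0.12 ± 0.21), Vnn1 (-0.15 ± 0.13), Cpt1a (-0.22 ± 0.12), Fgf21 (1.64 ± 1.13) and Ppara itself (-0.24 ± 0.17) did not pass. Of 23 mitochondrial fatty acid oxidation genes, 0 passed in edgeR (1 up and 1 down at an unadjusted p under 0.05, 0 in DESeq2, 1 up in limma-voom; 1 up adjusted over the list alone), with a median of -0.04 (limma camera adjusted p = 0.321). Among 12 genes of PPARg and lipid uptake, 0 rose and 1 fell (2 fell adjusted over the list alone), with a median of -0.39 (limma camera adjusted p = 0.00118, but adjusted p = 0.194 with an estimated correlation). That gene was Cidea, from 238 to 27 counts per group (-3.27 ± 0.61, edgeR adjusted p = 0.00516), which did not pass without STAM replicate 3 (adjusted p = 0.0633, the highest of 12 alternatives, the lowest being 2.79e-06). Cd36 was at 94.3 ± 7.97 and 97.1 ± 14.8 CPM, and its small difference changed sign with limma-voom (-0.0096).

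Of 16 bile acid synthesis genes, 2 rose and 2 fell (4 and 2 adjusted over the list alone), with a median of 0.15 (limma camera adjusted p = 0.777). Cyp7b1, the oxysterol hydroxylase of the acidic route and also a male-biased gene (chromosome 3, 18071950 to 18243338, minus strand), went from 167 ± 18.8 to 43.3 ± 8.41 CPM (edgeR adjusted p = 4.26e-06). Cyp8b1 (chromosome 9, 121914356 to 121916305, minus strand) went from 473 ± 83.6 to 285 ± 63.7 CPM (-0.73 ± 0.18, edgeR adjusted p = 0.0441), a call lost without STAM + Atglistatin replicate 4 or 5 or STAM replicate 1 or 3 (adjusted p = 0.108 to 0.230; range over 12 alternatives 6.37e-06 to 0.230). Cyp2c70 rose from 149 ± 26.7 to 276 ± 52.0 CPM (0.89 ± 0.16, edgeR adjusted p = 0.00494), a call lost without STAM + Atglistatin replicate 4 or STAM replicate 1 (adjusted p = 0.0509 to 0.0615; range over 12 alternatives 1.37e-08 to 0.0615). Cyp39a1, an oxysterol hydroxylase, rose by 2.03 ± 0.35. Cyp7a1 (0.33 ± 0.29) and Cyp27a1 (0.36 ± 0.12) did not pass. Slc10a2, the apical sodium-dependent bile acid carrier, which is outside the list of transporters, rose by 2.26 ± 0.31. It had fallen in STAM against chow (-3.01, edgeR adjusted p = 8.75e-06), so it is among the genes changed back. With Atglistatin it was lower than in chow without passing (-0.76, edgeR adjusted p = 0.177). Of the 16 bile acid and sterol transporters in the list, 0 rose and 1 fell (5 and 2 adjusted over the list alone; limma camera adjusted p = 0.465), the member that fell being Slco1a1 (-1.18 ± 0.21), which is also male-biased. Abcb11 (0.45 ± 0.12, edgeR adjusted p = 0.0945) passed with DESeq2 (adjusted p = 0.0226) and limma-voom (0.0351), in a range up to 0.371. Slc10a1 (0.09 ± 0.19) and Nr0b2 (-0.01 ± 0.25) did not pass. Of 11 FXR and bile acid regulators, 0 passed in edgeR, DESeq2 or limma-voom and 1 was higher at an unadjusted p under 0.05 (limma camera adjusted p = 0.313).

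No fibrosis gene passed in edgeR among 25 tested (3 lower at an unadjusted p under 0.05, 1 lower in DESeq2, 0 in limma-voom), with a median of -0.25 (limma camera adjusted p = 0.0232, but adjusted p = 0.737 with an estimated correlation). Col1a1 was at 34.0 ± 14.6 CPM in STAM and 16.6 ± 3.38 with Atglistatin (-1.04 ± 0.42, edgeR adjusted p = 0.368). It passed when only the 2 groups were fitted (edgeR adjusted p = 0.0267) and with no low-count filter (2.65e-05), in a range up to 0.801. Of 18 inflammatory genes, 0 passed in edgeR (1 up and 1 down at an unadjusted p under 0.05, 1 down in DESeq2, 0 in limma-voom; 1 down adjusted over the list alone; limma camera adjusted p = 0.788). Ccl2 was at 1.28 ± 1.29 and 1.46 ± 1.20 CPM, and Tnf had 0 counts with Atglistatin. Of 24 interferon response genes, 0 passed in edgeR, DESeq2 or limma-voom and 5 were lower at an unadjusted p under 0.05, with a median of -0.23 (limma camera adjusted p = 0.00360, but adjusted p = 0.165 with an estimated correlation). Of 16 hepatocyte genes, 1 rose and 2 fell (3 and 2 adjusted over the list alone; median -0.05, limma camera adjusted p = 0.872), with Alb higher by 0.63 ± 0.10 and Apob lower (-0.79 ± 0.14). The mitochondrial share was lower than in STAM by the values given above, and of 8 mitochondrially encoded transcripts 0 rose and 1 fell (5 fell adjusted over the list alone), with a median of -0.38 (limma camera adjusted p = 4.53e-06, but adjusted p = 0.142 with an estimated correlation). That transcript was mt-Nd5 (-0.68 ± 0.12), which overlaps mt-Nd6 on the other strand.

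In all, 226 genes passed, 132 higher and 94 lower, and 1285 had an unadjusted p under 0.05. The count was 131 without STAM replicate 1 (73 higher, 58 lower), 134 without STAM replicate 2 (77 and 57), 139 without STAM + Atglistatin replicate 5 (87 and 52) and 147 without STAM + Atglistatin replicate 4 (59 lower), and 392 with no low-count filter (203 higher, 189 lower). With only the 2 groups fitted, 145 were lower. The authors' deposited table held 282 genes under an adjusted p of 0.05, of which 216 were among the 226, all in the same direction. Of the lists, 15 passed limma camera, 6 higher and 9 lower, and 5 passed with an estimated correlation: cholesterol synthesis, fatty acid and triglyceride synthesis, male-biased, female-biased, and CAR and PXR genes. The list scores of the 15 separated all 3 treated libraries from every STAM library.

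**Figure D2:**
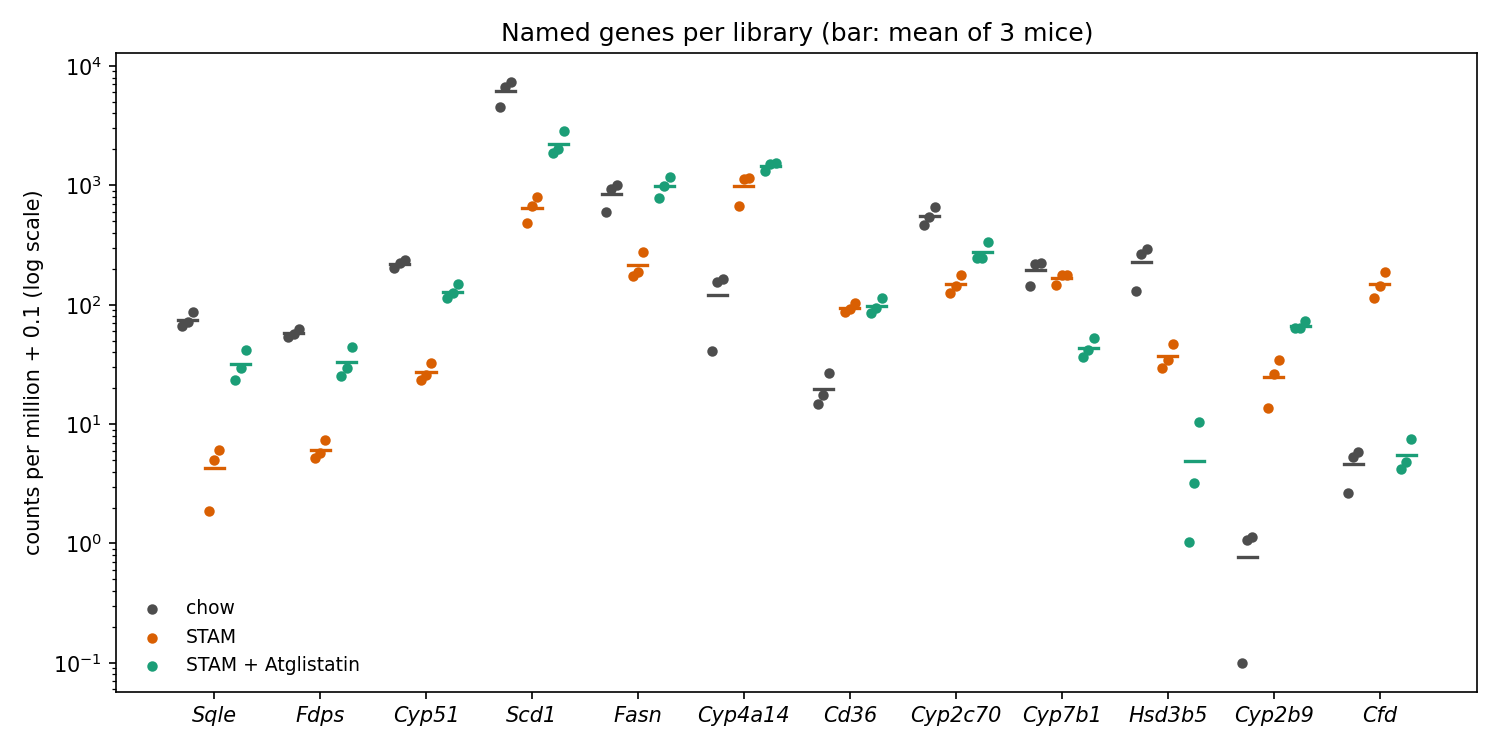
CPM plus 0.1 on a log axis for 12 named genes in each of the 9 libraries, with points for mice and bars for group means (n = 3). Cyp51 averaged 221 CPM in chow, 27.2 in STAM and 129 in STAM + Atglistatin, and Hsd3b5 averaged 229, 36.9 and 4.80.

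STAM + Atglistatin against chow asked how far treated mice stayed from healthy ones. PPARa targets were higher than in chow: Cyp4a14 was at 1452 ± 123 against 120 ± 69.0 CPM (3.59 ± 0.35, edgeR adjusted p = 4.34e-06; n = 3 each). Cd36 was at 97.1 ± 14.8 against 19.6 ± 6.23 CPM, and of 12 genes of PPARg and lipid uptake 4 rose and 0 fell (7 rose adjusted over the list alone), with a median of 0.99 (limma camera adjusted p = 1.47e-05, but adjusted p = 0.0948 with an estimated correlation). That count was 2 without STAM + Atglistatin replicate 5 or 6 or chow replicate 8 or 9 or with only the 2 groups fitted, and 7 without chow replicate 7. Of 18 male-biased genes, 0 rose and 17 fell (17 adjusted over the list alone), with a median of -1.94 (limma camera adjusted p = 5.34e-44, and adjusted p = 0.0133 with an estimated correlation). Among them Cyp7b1 fell by 2.17 ± 0.18. Of 10 female-biased genes, 6 rose and 0 fell (7 rose adjusted over the list alone), with a median of 3.06 (limma camera adjusted p = 6.50e-11, and adjusted p = 0.0133 with an estimated correlation).

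Of 25 PPARa targets, 12 rose and 0 fell (16 rose adjusted over the list alone), with a median of 0.45 (limma camera adjusted p = 2.99e-24, and adjusted p = 0.0133 with an estimated correlation). Of 25 cholesterol synthesis genes, 0 rose and 9 fell (12 fell adjusted over the list alone), with a median of -0.53 (limma camera adjusted p = 8.45e-13, but adjusted p = 0.0680 with an estimated correlation). The cholesterol count was 3 without STAM + Atglistatin replicate 5, 4 without replicate 4 of that group and 5 without chow replicate 8. Of 16 general hepatocyte genes, 0 rose and 8 fell (12 fell adjusted over the list alone), with a median of -0.49 (limma camera adjusted p = 4.56e-15, but adjusted p = 0.0728 with an estimated correlation). The hepatocyte count was 4 without STAM + Atglistatin replicate 5, and 5 without replicate 4 of that group or chow replicate 8 or 9. Of 16 bile acid synthesis genes, 0 rose and 2 fell (2 adjusted over the list alone), with a median of -0.12 (limma camera adjusted p = 0.0437, but adjusted p = 0.625 with an estimated correlation). These were Cyp2c70 (-1.01 ± 0.16) and Cyp7b1, while Cyp7a1 (0.24 ± 0.29), Cyp8b1 (-0.11 ± 0.18) and Cyp27a1 (-0.29 ± 0.12) did not pass. Cyp27a1 passed without chow replicate 7 (edgeR adjusted p = 0.0389, in a range up to 0.573 over 12 alternatives). Abcb11 fell by 0.58 ± 0.12 (edgeR adjusted p = 0.0106), a call lost without STAM + Atglistatin replicate 5 or chow replicate 8 or 9 (adjusted p = 0.0528 to 0.0570; range over 12 alternatives 0.000244 to 0.0570). Slc10a1 (-0.33 ± 0.19), Nr0b2 (-0.21 ± 0.25), Pnpla2 (0.43 ± 0.18), Ppara (0.10 ± 0.17), Fgf21 (-0.50 ± 1.03), Col1a1 (-1.13 ± 0.42) and Ccl2 (-1.29 ± 0.83) did not pass. Without chow replicate 7, Slc10a1 passed (edgeR adjusted p = 0.00546, in a range up to 0.839), as did Fgf21 (edgeR adjusted p = 0.0128, up to 0.953) at a fold change of the other sign (5.36). That Fgf21 value rests on chow libraries at 0 and 0.148 CPM. Col1a1 passed without chow replicate 8 (edgeR adjusted p = 0.0325) and with no low-count filter (2.27e-06), in a range up to 0.867.

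In all, 516 genes passed, 266 higher and 250 lower, and 1878 had an unadjusted p under 0.05. With library totals in place of TMM, 359 were higher and 184 lower, and with no low-count filter 379 were lower. The count was 309 and 312 without STAM + Atglistatin replicate 5 or 4 (177 and 164 higher, 132 and 148 lower), 316 without chow replicate 9 (169 and 147) and 322 without chow replicate 8 (143 lower). Without chow replicate 7 it was 757, with 381 lower. The authors' deposited table held 625 genes under an adjusted p of 0.05, of which 504 were among the 516, all in the same direction. Of the lists, 18 passed limma camera, 8 higher and 10 lower, and 3 passed with an estimated correlation: male-biased, female-biased and PPARa target genes. Of the 18, all 3 treated libraries lay beyond every chow library in list score, except for red blood cells (2 of 3), bile acid synthesis (1), fibrosis (0) and NRF2 genes (0).

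Of the genes changed in STAM, 96 changed back with Atglistatin, that is, passed in the opposite direction against STAM, which is 19.2% of 499 and 42.5% of 226. Of these, 72 were lower in STAM and higher with Atglistatin and 24 the reverse, while 20 genes changed the same way in both steps (13 lower, 7 higher). Lists drawn independently would give 2.63, 1.83 and 4.45 genes. Among the clearest of the 72 were Cyp51, Fdps, Msmo1 and the cytochrome P450 gene Cyp2c68 (log2 fold changes of -1.45 ± 0.12 and 1.68 ± 0.12 in the 2 steps). The clearest of the 24 were Cfd, the amino acid transporter gene Slc7a2 (173 ± 4.49, 339 ± 51.8 and 180 ± 6.91 CPM in chow, STAM and STAM + Atglistatin), Mup9 (79.5 ± 44.0, 316 ± 40.3 and 23.8 ± 2.58 CPM), the phosphatase gene Ppm1k (89.8 ± 11.9, 183 ± 10.3 and 96.3 ± 15.6 CPM) and Gpcpd1 (42.4 ± 13.8, 104 ± 29.3 and 41.9 ± 6.59 CPM). The rise of Mup9 in STAM may be reads moved between similar Mup copies, which stays open. The summed CPM of 22 Mup genes was 15312 ± 4759 in chow and 13259 ± 1193 in STAM, and Mup12 fell in STAM (-2.02). Against chow, 70 of the 96 genes changed back did not pass in STAM + Atglistatin and 26 did. Both comparisons use the same STAM libraries, which pushes the fold changes apart by chance: their covariance across genes was -0.133, against -0.0871 in simulated data with no effect. By other measures across genes the opposition was weaker than in those data, with a Pearson's r of -0.381 against -0.501 and opposite signs in 63.8% of genes against 66.6%. In 20 runs simulated after the data were seen, with the changes of the 499 genes in STAM and no effect of Atglistatin, a mean of 0.1 genes changed back and at most 1. Genes are not independent replicates. The count was 59 without STAM replicate 1 and 164 with no low-count filter.

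**Figure D3:**
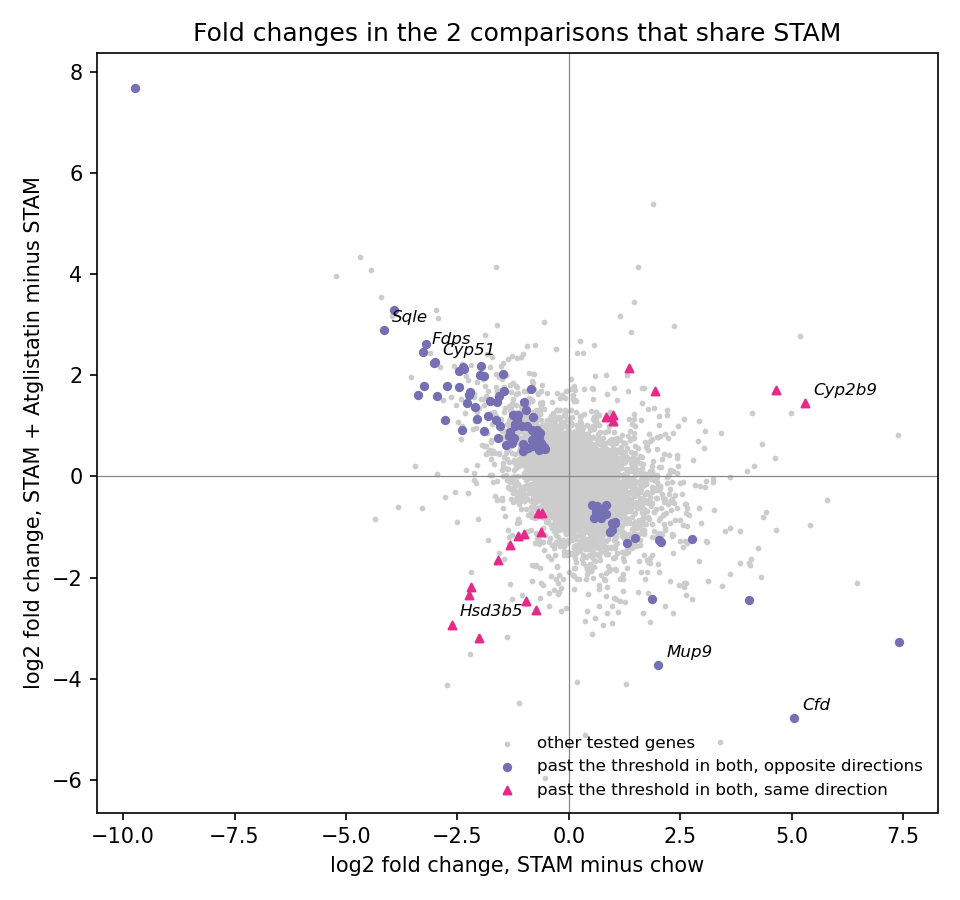
Log2 fold change in STAM against chow (horizontal) and in STAM + Atglistatin against STAM (vertical) for 12660 tested genes, with the 96 that passed in opposite directions as circles and the 20 that passed in the same direction as triangles. The circle farthest to the upper left is Chrna4, singled out after its values were seen, which had 0 counts in all STAM libraries, so its fitted fold change is no bound.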

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

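Library totals without TMM were chosen after the data were seen, and the other alternatives before. DESeq2 called 639, 287 and 648 genes in STAM against chow, STAM + Atglistatin against STAM, and STAM + Atglistatin against chow, of which 489, 219 and 508 were shared with edgeR. DESeq2 size factors gave 497, 224 and 516 (495, 224 and 514 shared), and all 163 values of named genes kept direction and side of the threshold. Library totals gave 552, 222 and 543, limma-voom 729, 293 and 581, and a fit to 2 groups 462, 314 and 374. With no low-count filter, 392 genes passed in STAM + Atglistatin against STAM and 164 changed back. In that comparison this setting gave the lowest edgeR adjusted p of all alternatives for Col1a1 (2.65e-05) and Cyp4a14 (0.00155), which had not passed. Where a range over alternatives is given, a low end far below the main fit is no measure of the strength of a call. Requiring an absolute log2 fold change of at least 1 left 230, 123 and 256 genes, and 48 changed back, as that rule only removes calls. An estimated correlation left 3, 5 and 3 lists, and fry called 8, 7 and 11. Leaving out 1 library gave 291 to 724, 131 to 191 and 309 to 757 genes, and 59 to 123 changed back. Counts moved by over 1.5 times without STAM replicate 1 or 2 (291 and 312) in STAM against chow, without those or STAM + Atglistatin replicate 4 or 5 (131, 134, 147 and 139) in STAM + Atglistatin against STAM, and without STAM + Atglistatin replicate 4 or 5 or chow replicate 8 or 9 (312, 309, 322 and 316) in STAM + Atglistatin against chow. The 59 genes changed back were without STAM replicate 1. A pseudocount and a filter for normalised values were not tried, as the values are counts.

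Signs reversed in genes that had not passed with all libraries, and of these Fgf21 in STAM + Atglistatin against chow passed without chow replicate 7 (5.36, edgeR adjusted p = 0.0128). With limma-voom they were Col1a1 (0.42) and Fgf21 (1.66) in STAM against chow, Cd36 (-0.0096) in STAM + Atglistatin against STAM, and Fgf21 (3.22) in STAM + Atglistatin against chow. Leaving out 1 library, log2 fold changes in STAM against chow ranged from -0.47 to 0.88 for Col1a1, -0.57 to 0.17 for Cyp7a1 and -2.96 to 3.72 for Fgf21. In STAM + Atglistatin against STAM they ranged from -0.54 to 1.42 for Ccl2, -0.084 to 0.13 for Cd36, -0.10 to 0.81 for Cyp7a1, -0.38 to 0.22 for Nr0b2 and -0.26 to 0.14 for Pnpla2. In STAM + Atglistatin against chow they ranged from -0.19 to 0.46 for Cyp7a1, -0.23 to 0.077 for Cyp8b1, -1.08 to 5.36 for Fgf21, -0.57 to 0.021 for Nr0b2 and -0.14 to 0.26 for Ppara. Fgf21 was at 13.8 CPM in chow replicate 7 and at 0 and 0.148 in the other chow libraries. Its value of 5.36 without replicate 7 thus rests on chow values near 0. Col1a1 was likewise at 70.5 CPM in chow replicate 7 and at 13.7 and 23.3 in the others. For the other genes the cause was not tested. Depth limits genes such as Tnf, with at most 1 count per group.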

Other observations

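In STAM against chow, of 20 acute phase genes, 5 rose and 6 fell (7 and 7 adjusted over the list alone; limma camera adjusted p = 0.543), with Saa2, an acute phase apolipoprotein with a closely similar relative, higher by 2.07 ± 0.26 and Apcs, serum amyloid P, lower by 1.84 on the log2 scale (-1.84 ± 0.23). The list's median was 0.02 and its mean 0.23, while camera's direction was down. Of 12 fetal and liver tumour genes, 2 rose and 0 fell (5 and 1 adjusted over the list alone), with a median of 0.82 (limma camera adjusted p = 0.00178, but adjusted p = 0.365 with an estimated correlation); the score of this list was 1.21 in chow replicate 7 and -0.77 and -0.44 in the other chow libraries. Of 18 CAR and PXR genes, 5 rose and 4 fell (6 and 5 adjusted over the list alone; limma camera adjusted p = 0.746), among them Cyp2c29 (-2.78 ± 0.21). Of 13 Kupffer cell markers, 0 rose and 1 fell, the iron exporter gene Slc40a1 (-0.63 ± 0.12; limma camera adjusted p = 0.450), and the list's median of -0.06 turned to 0.02 with library totals. Summed CPM of the adipocyte markers was 122 to 194 in the STAM libraries and 4.46 to 16.1 in the others, and Cfd made up 149 ± 37.2 in STAM, 4.51 ± 1.74 in chow and 5.44 ± 1.77 in STAM + Atglistatin. Summed CPM of skeletal muscle markers was 20.5 in STAM + Atglistatin replicate 6 and 0.708 to 2.40 elsewhere.

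In STAM + Atglistatin against STAM, 2 of 12 fetal and liver tumour genes rose and 0 fell (2 adjusted over the list alone), with a median of 0.27 (limma camera adjusted p = 0.0370, but adjusted p = 0.607 with an estimated correlation). They were Ccnd1, cyclin D1, which overlaps LTO1 on the other strand (1.31 ± 0.23), and Cdkn1a, whose call is lost without any 1 of the STAM libraries or STAM + Atglistatin replicate 4 or 5 (edgeR adjusted p from 0.0508 to 0.121, and 3.06e-52 to 0.123 over 12 alternatives). The call of Cdkn1a held with only the 2 groups compared fitted. Of 14 periportal hepatocyte genes, 0 rose and 2 fell (5 fell adjusted over the list alone), with a median of -0.20 (limma camera adjusted p = 2.03e-05, but adjusted p = 0.0582 with an estimated correlation), among them Sds, serine dehydratase, which overlaps Plbd2 on the other strand (-0.95 ± 0.14). Of 23 proliferation genes, 0 passed in edgeR, DESeq2 or limma-voom and 1 was higher at an unadjusted p under 0.05 (limma camera adjusted p = 0.381). Median fold change, mean fold change and camera's direction differed in sign for some lists, none of which passed camera. In STAM against chow these were the FXR, acute phase, NRF2, proliferation, lymphocyte and immediate early lists, and in STAM + Atglistatin against STAM the lipolysis, clock, pericentral and cholangiocyte lists. In STAM + Atglistatin against chow they were the glucose, acute phase, proliferation, Kupffer cell, recruited macrophage and stellate cell lists.

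All tests of explanations given here, and the splits of the samples, were chosen after the results were seen, as were Adipoq, Adrb3, Abca1 and Abcg8 as genes to name.

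Male-biased genes were lower and female-biased genes higher with Atglistatin. Libraries from female animals are argued against by summed CPM of Y-linked genes, which stood at 146 ± 11.5 in STAM and 148 ± 4.92 with Atglistatin, a ratio of 1.01. Reads moving between copies of the Mup genes are argued against by the family total of 22 genes, which was lower by a log2 ratio of -1.36. Lower growth hormone signalling may contribute, since 9 of 10 growth hormone axis genes had lower means, with 0 past the threshold in edgeR or DESeq2, 1 in limma-voom and 5 at an unadjusted p under 0.05, but the list had an adjusted p of 0.0582 by limma camera with an estimated correlation, so this stays open. No hormone level or body weight was analysed here.

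Cholesterol synthesis genes were lower in STAM and higher again with Atglistatin. Scaling is argued against by list medians of -1.80 and 1.46 with library totals. A lower share of hepatocytes in STAM is argued against as the whole cause by hepatocyte list medians of -0.49 against chow, where the cholesterol median was -1.90, and -0.049 with Atglistatin against STAM, but a part in the fall stays open, and Alb (-1.03 ± 0.10, then 0.63 ± 0.10) moved with it. A different sampling time is argued against for the Atglistatin step by a median absolute log2 fold change of 0.0969 over 7 clock output genes, but stays open against chow, as does feeding state: the median was 0.356 and Tef, 1 of the 7, rose (0.70 ± 0.18, edgeR adjusted p = 0.0295; 0.0634 to 0.139 without chow replicate 7 or 9 or any STAM replicate, and 5.53e-05 to 0.139 over 12 alternatives). A higher sterol content of STAM livers may hold the pathway down: Abca1, Abcg5 and Abcg8 had a median of -0.28 with Atglistatin, too small and too few genes to decide.

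Cfd was higher in STAM and lower with Atglistatin. Adipose tissue carried into STAM samples is argued against by the 6 other adipocyte markers, whose summed CPM was 1.45 times that of chow while Cfd was at 33.1 times, and by Adipoq at 0.971 ± 1.32 CPM in chow and 0.117 ± 0.120 in STAM. Of the 6, only Adrb3 had enough counts to be tested, and it was higher in STAM at an edgeR unadjusted p under 0.05. The sum of the 6 did not fall with Atglistatin (6.26 ± 0.790 CPM in STAM and 6.28 ± 2.06 with it). A fat-storage programme under PPARg may account for it, as Cidea rose and fell likewise (the fall had an adjusted p of 0.0633 in edgeR without STAM replicate 3, and 2.79e-06 to 0.0633 over 12 alternatives). No other member of the PPARg list passed in that fall. Cd36 of the same list rose but did not fall, with 14.6 to 26.6 CPM in chow, 87.5 to 103 in STAM and 84.5 to 113 with Atglistatin. The PPARg list had an adjusted p of 0.194 by limma camera with an estimated correlation in STAM + Atglistatin against STAM, which leaves this open.

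The 10 splits of 6 samples into 3 and 3 are too few for a share under 0.05. The real splits gave 499, 226 and 516 genes in the 3 comparisons, in the order above, with 0, 5 and 0 as the highest of the others, so that 1 of 10 was as large in each. For lists, the real splits gave 14, 15 and 18, with 17, 11 and 16 as the highest of the others, and 4, 1 and 1 of 10 were as large. For genes changed back, 2 of 100 splits of the 9 samples, the real one with 96 included, were as large, a share under 0.05. These splits treat all 9 libraries as alike, which they are not. The share therefore does not bear on whether Atglistatin changed genes back. The highest other, 99, put the 3 chow libraries in the middle group and mixed STAM and STAM + Atglistatin libraries in the outer groups, as did one with 92, which points to a structure of the samples in which chow stands apart from the rest.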
